A study of Mus musculus with 13 samples.

How the data were processed

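The values analysed were the transcript tables of 13 libraries of pooled, laser-captured hair follicles, which the authors made with TopHat and Cufflinks on the mm10 genome, per the submitters' processing notes, with no version given for either tool. Per the file headers each table lists the FPKM with its confidence bounds and the coverage of 1 RefSeq transcript per line. FPKM as deposited are fragments per transcript length and per mapped fragments, as Cufflinks estimated them, and no further scaling by the authors is stated in the labels. The coverage signal, per the file headers, is the estimated read depth over each transcript and served only to compare depth. Aligned bases are the sum of coverage times transcript length, and relative depth is coverage per FPKM over that of the median library. No count table or count-based tool was used.

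Each table held 31580 transcripts. FPKM was summed per gene symbol over transcripts, which gave 23444 symbols. The 45 symbols listed on more than 1 chromosome name were summed as well. Of all symbols, 3 had a failed Cufflinks estimate in at least 1 of 4 libraries and were left out. The 356 transcripts of each table marked as too shallow for an estimate kept their listed value. Genes with a mean of at least 1 FPKM over the 12 libraries of the 4 groups were tested, which left 10051. The mixture of wild types may hold RNA of the same animals as the other wild types and was kept out of the fits reported, entering only as an alternative.

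Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with empirical Bayes moderation and a mean-variance trend. A single fit of the 4 group means over the 12 libraries gave the 8 comparisons, and the groups shared 1 estimate of the spread. Tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. No batch is stated in the labels, and no covariate was fitted. Tables were read and summed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

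The 25 gene lists were fixed before the files were seen. Each was tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and the rotation test fry were alternatives. Camera compares a list with all other genes, so a list can pass upward while its median is below 0 when most genes are lower.

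Genes were named by a rule also fixed before the files were seen. It took the 5 targeted genes in every comparison with wild type. It added the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 FPKM and no overlap between the wild-type and mutant libraries, and up to 4 members of each list with the smallest adjusted p. Between mutants it took the 5 largest rises and the 5 largest falls. Symbols of small RNAs and of predicted genes were not named.

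The overlap of calls was set beside that of independent lists and beside 50 simulations of unchanged groups against the same wild types. Clustering used average linkage on 1 minus Pearson's r. The test of genotype in the clustering was an exact permutation of the labels of the 9 mutant libraries.

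Alternatives fixed in advance were a pseudocount of 0.1, no filter, a filter at 5 FPKM, quantile normalization, median-ratio scaling, moderation without trend, robust moderation, array weights, the mixture as a further wild type, a fit of only the groups compared, the mouse line or the replicate number as a block, and each library left out in turn. Chosen after the values had been seen were separate spreads for wild-type and mutant libraries, scaling by the FPKM sum, each genotype averaged to 1 value, wild types 1 and 3 alone for the RBPjk-null comparison, the 9 mutant libraries alone without a block, and repeats of some settings for the criterion of the series, the overlap, the clustering, the lists and single genes.

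The procedure was tried on simulated values with the means and spreads of these data over 10051 genes in 5 draws. With 200 genes changed and equal spreads, the comparison of all mutants with wild type recovered 86.3% of genes changed 1.5-fold and 98.8% of those changed 2-fold, and 3.42% of calls were false. For RBPjk-null against wild type these values were 68.7%, 97.0% and 4.8%, and for the joined Notch1&2-null and Psen1&2-null against RBPjk-null libraries 82.1%, 98.8% and 3.3%. In 20 draws camera called a list of 20 genes shifted by 0.5 on the log2 scale each time, and it called none of 400 unchanged lists. Genes were drawn independently of one another there, so these draws cannot tell how often camera calls unchanged lists of correlated genes. In these data the estimated correlation was 0.0934 for the hair shaft keratins and 0.514 for the fibroblast markers.

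The simulations also showed a limit of the shared spread. With the larger wild-type spread seen here and 200 genes changed, 30.7% of calls were false for all mutants against wild type and 15.9% for RBPjk-null, and with 2000 genes changed 12.3% and 7.6%. With separate spreads these values were 8.75% and 9.11%, and 4.85% and 4.54%. Counts of genes called against wild type are therefore given with both. The comparison of the joined mutants with RBPjk-null had 3.33% false calls with the shared and 7.96% with separate spreads.

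The confidence bounds listed with each FPKM were not used, and limma estimated the spread from the differences between libraries alone. The simulations drew values independently between libraries and between genes, and held no shared animals. Members of the Krt, Krtap, Stfa, Hist and globin gene families share sequence, and their reads may be split wrongly between members. Changes of total RNA per cell cannot be seen in FPKM.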

Results

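Hair follicles were cut by laser capture from frozen skin sections of mice at postnatal day 3, and their RNA was sequenced as pools of follicles. Per the labels, 3 libraries came from follicles without the receptors Notch1 and Notch2, 3 from follicles without the presenilins Psen1 and Psen2, and 3 from follicles without RBPjk. Presenilins are the catalytic subunits of the protease that releases the Notch intracellular domain, and RBPjk is the DNA-binding partner of that domain. Wild types 1, 2 and 3 came from the Notch, Psen and RBPjk mouse lines in that order, and a further library was a mixture of wild types from these lines. The mixture is described by its values and entered tests only as an alternative. Levels are FPKM per gene, as mean ± SD over n = 3 libraries. Fold changes are differences of log2(FPKM + 1), a scale that understates the change of low genes.

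The 13 libraries held 0.669 to 0.929 Gb of aligned bases by the coverage the authors listed. Relative depth ran from 0.889 in the wild type of the Notch line to 1.37 in Notch1&2-null library 2. It averaged 0.947 in wild types, 1.16 in Notch1&2-null, 1.01 in Psen1&2-null and 1.13 in RBPjk-null libraries. Between 9588 and 10325 genes reached 1 FPKM, and the 10 most abundant genes took 12.3% to 19.4% of all FPKM. The number of animals in each pool was not given in the sources used here, so libraries of a group may share animals. The p-values below measure the spread between pooled libraries and are too small where animals were shared.

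The wild types differed among themselves more than the mutant libraries did. The median SD of a gene's log2 level was 0.182 in wild types, 0.0951 in Notch1&2-null, 0.105 in Psen1&2-null and 0.13 in RBPjk-null libraries. Each wild type came from another mouse line, while each mutant group came from 1 line. The mixture differed from the mean of the 3 wild types by a median of 0.124 on the log2 scale, against 0.214 to 0.246 for each wild type against the mean of the other 2.

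Sex-linked genes differed between the groups. Xist, which is transcribed from the inactive X chromosome, stood at 54.0 FPKM in the wild type of the Psen line and at 0.0297 and 0.0473 FPKM in those of the Notch and RBPjk lines. It measured 27.5 ± 0.622 FPKM in Notch1&2-null, 49.1 ± 1.66 in Psen1&2-null and 0.0226 ± 0.00702 in RBPjk-null libraries. The Y-linked gene Eif2s3y was listed at 0 in all Psen1&2-null libraries and in the wild type of the Psen line, and measured 3.90 ± 0.396 FPKM in Notch1&2-null and 12.8 ± 2.43 in RBPjk-null libraries. Sex therefore varied together with genotype, and a sex difference could not be separated from a genotype difference for Notch1&2-null and Psen1&2-null libraries or between the mutants. For RBPjk-null libraries, wild types 1 and 3 gave controls of like Xist and Y-linked expression.

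The targeted genes were examined first. Notch1 (chromosome 2, 26457902 to 26503822, mm10) measured 11.6 ± 1.54 FPKM in wild types and 1.91 ± 0.0736 in Notch1&2-null libraries, which is 16.4% of wild type (log2 fold change −2.11, SE 0.11, limma with Benjamini-Hochberg adjusted p = 2.15e-07). Notch2 (chromosome 3, 98013538 to 98150367) stood at 8.58 ± 0.277 FPKM in wild types and 4.63 ± 0.0774 in Notch1&2-null libraries, 54.0% of wild type (−0.77, adjusted p = 1.1e-05). Psen1 (chromosome 12, 83688563 to 83735199) went from 7.11 ± 1.58 FPKM to 3.05 ± 0.240 in Psen1&2-null libraries, 42.9% of wild type (−0.99, SE 0.12, adjusted p = 1.36e-04). Rbpj (chromosome 5, 53555779 to 53657445) went from 4.93 ± 0.387 to 3.05 ± 0.206 FPKM in RBPjk-null libraries, 61.9% of wild type (−0.55, adjusted p = 8.03e-04). Psen2 (chromosome 1, 180227004 to 180256300) was near the filter on low values in every group, at 0.890 ± 0.543 FPKM in wild types and 0.765 ± 0.333 in Psen1&2-null libraries (adjusted p = 0.816). Its difference of −0.08 became 0.01 with median-ratio scaling, 0.14 without the wild type of the RBPjk line and 0.03 without Psen1&2-null library 3, so these values gave no check of the Psen2 label.

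The labels do not say which exons were removed, and the values are sums over whole transcripts, so reads from a remaining part of a targeted gene count toward its level. Laser-captured follicles can also hold cells in which the gene was not removed. Notch1 was lower in the other mutants too, at 66.2% of wild type in Psen1&2-null (adjusted p = 0.00416) and 53.7% in RBPjk-null libraries (adjusted p = 4e-04). Notch2 was lower there as well, at 71.8% (adjusted p = 7.23e-04) and 79.6% (adjusted p = 0.00629, but 0.0953 with quantile normalization and 0.0681 with median-ratio scaling). Among genes that Notch signalling is known to activate, Heyl measured 4.80 ± 0.611 FPKM in wild types and 0.696 ± 0.0388, 0.915 ± 0.112 and 1.41 ± 0.171 in Notch1&2-null, Psen1&2-null and RBPjk-null libraries. Hes1 measured 24.2 ± 3.25 FPKM in wild types and 9.29 ± 2.49, 9.0 ± 1.85 and 10.8 ± 1.14 in the mutants in the same order, and Nrarp 7.79 ± 1.22 against 3.06 ± 0.266, 2.89 ± 0.734 and 4.98 ± 0.615. Over all mutants the log2 fold change was −1.54 for Heyl (SE 0.080, adjusted p = 1.38e-07), −1.25 for Hes1 (adjusted p = 1.49e-04) and −0.95 for Nrarp (adjusted p = 1.41e-04). Hes5 was listed at 0 in all wild types and in all mutant libraries except Notch1&2-null library 2, at 0.0901 FPKM.

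**Figure D1:**
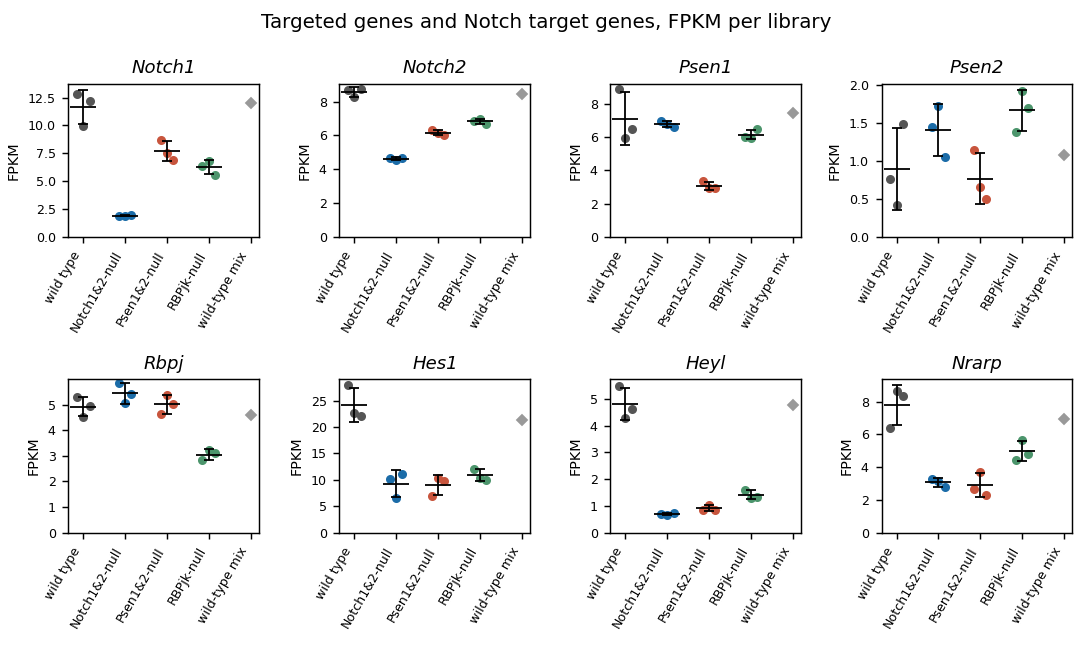
FPKM of the 5 targeted genes and of the Notch target genes Hes1, Heyl and Nrarp in each library, with the mean and SD of each group of 3 and the wild-type mixture as a single point. Each targeted gene other than Psen2 was lower in the follicles labelled as lacking it, and Heyl was lower in each of the 9 mutant libraries (0.662 to 1.60 FPKM) than in each wild type (4.30 to 5.48 FPKM).

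The comparison of all mutants with the wild types asked which genes differed on loss of Notch signalling. Keratins of the hair follicle were lower in the mutants. Of 14 hair shaft keratin genes tested, 12 fell and none rose (12 adjusted over the list alone, 1 higher and 12 lower with quantile normalization; camera adjusted p = 2.15e-07, adjusted p = 0.0944 with an estimated correlation). Krt33a measured 95.4 ± 10.8 FPKM in wild types against 16.8 to 29.9 in the mutant groups (−2.06, SE 0.10, limma adjusted p = 8.81e-08), Krt31 42.5 ± 2.02 against 7.74 to 18.2 (−1.60) and Krt33b 23.9 ± 9.05 against 1.30 to 3.24 (−2.86). Krt33a and Krt33b are near-identical in sequence, so the split of reads between them is uncertain.

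Genes of the inner root sheath and medulla, the layers that mould and fill the hair shaft, held the keratins with the largest falls. Of 19 tested, 11 fell and none rose (11 adjusted over the list alone, 1 higher and 11 lower with quantile normalization; camera adjusted p = 1.53e-04, adjusted p = 0.597 with an estimated correlation). Krt72 and Krt26, keratins of the inner root sheath cuticle, went from 83.4 ± 5.14 to between 0.153 and 8.89 FPKM (−4.27, SE 0.089, limma adjusted p = 6.53e-11) and from 49.9 ± 3.63 to between 0.272 and 5.57 FPKM (−3.83, SE 0.064, adjusted p = 9.97e-12). Krt73 measured 111 ± 26.4 FPKM in wild types and 26.6 to 36.8 in the mutants (−1.82). Crym, which encodes the thyroid hormone-binding protein mu-crystallin, measured 34.7 ± 5.80 and 1.00 to 5.11 (−3.36, adjusted p = 5.25e-08).

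**Figure D2:**
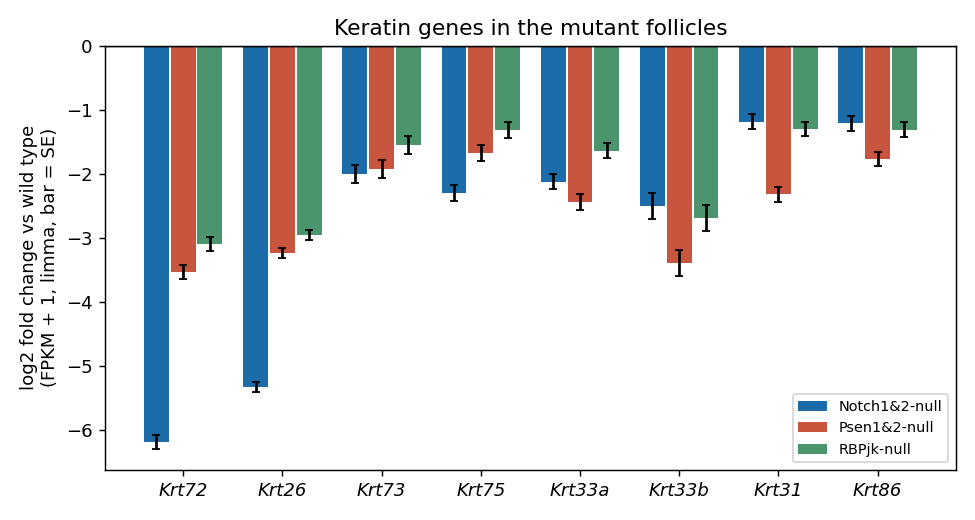
Log2 fold change of 8 keratin genes in each mutant genotype against the wild types, from limma on log2(FPKM + 1), with bars for the standard error. Each of the 8 genes was lower in each genotype, and Krt72 and Krt26 were lowest in Notch1&2-null follicles (−6.19 and −5.32).

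Among the genes with the largest changes, keratin-associated proteins, the matrix proteins around hair keratin filaments, went both ways. Krtap19-1 (−4.76), Krtap19-4 (−4.20), Krtap19-5 (−3.80, limma adjusted p = 5.17e-09), Krtap16-1 (−3.56) and Krtap19-3 (−3.28) fell, while Krtap4-9 rose (2.09, adjusted p = 3.04e-07). Krtap19-1 measured 216 ± 52.0 FPKM in wild types and 1.57 to 16.4 in the mutant groups. The largest rises were those of Stfa2l1 (3.21), Stfa3 (2.97), both of the stefin A protease inhibitors, Saa3 (2.93), S100a9 (2.85), Lcn2 (2.33), Hp (1.94) and Serpina3n (1.93). Members of the Krtap and Stfa families share near-identical stretches, so levels of single members are uncertain.

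Regulators of the hair matrix moved both ways. Of 21 tested, 10 fell and 4 rose (10 and 4 adjusted over the list alone, camera adjusted p = 0.526), and 7 rose and 8 fell with quantile normalization. The hair desmosomal cadherin Dsg4 went from 29.0 ± 3.48 to between 6.24 and 7.47 FPKM (−1.91, limma adjusted p = 1.43e-08), and the transcription factor Hoxc13 from 80.9 ± 10.4 to between 40.7 and 46.7 (−0.85). The orphan receptor Gprc5d (−1.35) and the transcription factor Grhl1 (−0.93) also fell. Of 24 outer root sheath and basal keratinocyte genes, 10 rose and 4 fell (12 and 4 adjusted over the list alone, camera adjusted p = 1.03e-04, adjusted p = 0.597 with an estimated correlation), and 15 and 3 with quantile normalization. The chemokine Cxcl14 (1.05) and the receptor Lgr6 (1.1) rose, whereas the companion layer keratin Krt75 (−1.76, 66.3 ± 12.0 to between 12.5 and 25.9 FPKM) and Sox9 (−0.71) fell. Of 16 genes of interfollicular epidermal differentiation, 5 rose and 5 fell (5 and 5 adjusted over the list alone, camera adjusted p = 0.0584), with the test upward, a median of 0.20 and a mean of −0.07, and 9 rose and 4 fell with quantile normalization. Ivl (−1.25), Cnfn (−2.61) and Calml3 (−0.97) fell and Calm4 rose (1.21).

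Of the signalling lists, the Hedgehog pathway and the FGF, EGF and IGF genes passed the list test. Of 12 Hedgehog pathway genes, 5 rose and none fell (6 rose adjusted over the list alone, 9 higher and 0 lower with quantile normalization; camera adjusted p = 1.84e-06, adjusted p = 0.405 with an estimated correlation), among them the pathway targets Gli1 (2.37 ± 0.337 to between 3.51 and 4.70 FPKM, 0.62, limma adjusted p = 1.44e-04) and Ptch2 (0.72) and the ligand Shh (0.43). Of 22 FGF, EGF and IGF genes, 9 rose and 5 fell (9 and 5 adjusted over the list alone, 11 higher and 4 lower with quantile normalization; camera adjusted p = 0.00309, adjusted p = 0.62 with an estimated correlation). Igfbp3, an IGF-binding protein, rose (5.15 ± 1.28 to between 11.3 and 20.2 FPKM, 1.41), as did the EGF receptor ligand Areg (0.76), and the ligand Tgfa fell (−0.92). Of 11 Notch target genes, 6 fell and 1 rose (6 and 1 adjusted over the list alone). Of 23 genes of the Notch machinery, 8 fell and 3 rose (8 and 3 adjusted over the list alone). Neither list stood apart from the other genes (camera adjusted p = 0.203 and 0.925). The rotation test fry, which asks whether a list changed at all and not whether it stood apart, called both lower (adjusted p = 1.47e-04 and 0.0376).

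Of 20 BMP and TGF-beta genes, 4 rose and 7 fell (5 and 8 adjusted over the list alone, camera adjusted p = 0.524, upward, with a median of −0.21 and a mean of −0.07), and 7 rose and 3 fell with quantile normalization. Id4 fell (−1.27), and the receptor Tgfbr2 (0.70) and ligand Tgfb2 (0.67) rose. Of 19 Wnt pathway genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.309, upward, with a median of −0.07 and a mean of −0.03), and here too 7 rose and 3 fell with quantile normalization. The Wnt antagonist Sfrp2 rose (0.93, 1.91 ± 0.322 FPKM in wild types and 9.09 ± 1.51 in RBPjk-null libraries), and Sfrp1 fell (−0.48). Of 30 cell cycle genes, 11 fell and none rose (12 fell adjusted over the list alone, camera adjusted p = 0.215), with Top2a at −0.43 and Ccne2 at −0.49, and 6 fell with quantile normalization. Of 15 immediate early and stress genes, 1 rose and none fell (1 adjusted over the list alone, camera adjusted p = 0.0584), the rise being that of Ier3 (0.44).

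Inflammatory genes and immune markers were higher in the mutants. Of 11 alarmin and inflammation genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 4.65e-07, adjusted p = 0.276 with an estimated correlation). S100a9, a subunit of the antimicrobial protein calprotectin, went from 0.888 ± 0.413 to between 7.28 and 20.4 FPKM (limma adjusted p = 2.47e-08), Lcn2 from 0.637 ± 0.507 to between 5.95 and 7.80, and the chemokine Ccl2 from 0.910 ± 0.308 to between 3.28 and 8.18 (1.65). Of 18 immune cell markers, 12 rose and none fell (13 rose adjusted over the list alone, camera adjusted p = 2.43e-11, adjusted p = 0.198 with an estimated correlation). The myeloid gene Tyrobp went from 4.16 ± 1.2 to between 7.67 and 26.5 FPKM (1.47), and Lyz2 from 19.5 ± 5.46 to between 20.5 and 110.3 (1.14).

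Markers of other cell types that a captured follicle could hold moved as follows. Of 22 dermal fibroblast and sheath markers, 7 rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 2.87e-05, adjusted p = 0.597 with an estimated correlation), and 14 rose and 1 fell with quantile normalization. Thy1 (1.06) and Dcn (0.65) were among the rises. Of 17 dermal papilla markers, 7 rose and 5 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.0202, adjusted p = 0.62 with an estimated correlation). This call was lost without the wild type of the Notch line (0.0607), without RBPjk-null library 1 (0.0511) and with quantile normalization (0.0861). Of 16 melanocyte markers, 10 fell and 1 rose (11 and 1 adjusted over the list alone, camera adjusted p = 0.00746, adjusted p = 0.644 with an estimated correlation), with the pigment enzyme gene Tyrp1 going from 64.9 ± 14.6 to between 22.2 and 47.6 FPKM (−0.89). Of 10 sebocyte markers, 7 fell and none rose (7 adjusted over the list alone, camera adjusted p = 0.0202, adjusted p = 0.597 with an estimated correlation), among them Elovl3 (−0.94) and Soat1 (−1.1). Of 10 adipocyte markers, 5 fell and 1 rose (5 and 2 adjusted over the list alone, camera adjusted p = 0.443), with Car3 going from 235 ± 37.8 to between 106 and 133 FPKM (−0.93).

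Camera called no small list. Of 6 endothelial and pericyte markers, 1 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.701, upward, with a median of −0.02 and a mean of −0.06). Of 4 muscle genes, 1 fell (1 adjusted over the list alone, camera adjusted p = 0.639), which was Myl1. Limma called none of the 5 nerve and Schwann cell markers, 4 blood cell genes and 6 sex-linked genes, over all genes or adjusted over the list alone, and at an unadjusted p under 0.05 only 1 nerve marker passed, with camera adjusted p = 0.176, 0.811 and 0.594. For the blood cell and sex-linked lists the test pointed upward, with medians of −0.29 and −0.48 and means of −0.07 and −0.005.

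Across all 10051 genes tested, limma called 3432 at a Benjamini-Hochberg adjusted p under 0.05, 676 higher and 2756 lower in the mutants (80.3% lower). The median of all genes was −0.12 on the log2 scale, against −0.12 in Notch1&2-null, −0.15 in Psen1&2-null and −0.09 in RBPjk-null libraries compared with wild type, so changes of single genes are to be read against that shift. Quantile normalization gave 1624 higher and 1576 lower, and median-ratio scaling 1663 higher and 1614 lower. With separate spreads for wild-type and mutant libraries the count was 1860 (369 higher, 1491 lower), and with each genotype averaged to 1 value it was 539. Leaving out wild type 1 gave 1024 higher and 2023 lower, and leaving out wild type 2 gave 433 higher and 2980 lower. Scaling by the FPKM sum gave 1106 higher and 2160 lower. In all, 369 genes were called higher and 1285 lower under the deposited scaling, both other scalings and the separate spreads. Genes called with at least a 2-fold difference numbered 48 higher and 136 lower, and 67 and 100 with quantile normalization.

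The design text of the series gives 2047 genes with at least a 1.5-fold difference at p under 0.05 in the mutants. By the same 2 bounds on the values here, with the unadjusted limma p, 710 genes passed over all mutants, 209 higher and 501 lower. Of these, 339 also differed by at least 1.5-fold the same way in each of the 3 genotypes. With the adjusted p, 690 genes passed, and with a pseudocount of 0.1 in place of 1, 1281 passed. By the unadjusted p and the 1.5-fold bound, 1774 genes passed in 1 or more genotypes, each compared with wild type. The tool and pseudocount behind the stated number were not given in the sources used here, so the counts may differ by method.

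In Notch1&2-null follicles, Krt72 and Krt26 of the inner root sheath cuticle were almost absent, while Krt73, also of the cuticle, measured 26.6 ± 1.51 FPKM against 111 ± 26.4 in wild types. Krt72 measured 0.153 ± 0.0763 FPKM against 83.4 ± 5.14 in wild types (−6.19, SE 0.11, limma adjusted p = 9.48e-12) and Krt26 0.272 ± 0.0786 against 49.9 ± 3.63 (−5.32, SE 0.078, adjusted p = 2.37e-12). Krtap19-1 (−6.40), Krtap19-4 (−5.24), Krtap19-5 (−4.89) and Crym (−4.16) were also among the largest falls. Stfa2l1 (3.38), Saa3 (2.93), S100a9 (2.86) and Stfa3 (2.71) rose the most. Of 14 hair shaft keratins 11 fell and 1 rose (11 and 1 adjusted over the list alone, camera adjusted p = 7.68e-06, adjusted p = 0.212 with an estimated correlation). Of 19 inner root sheath and medulla genes 10 fell and none rose (10 adjusted over the list alone, 4 higher and 10 lower with quantile normalization; camera adjusted p = 0.00599, adjusted p = 0.661 with an estimated correlation).

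Signalling genes of the Notch1&2-null follicles included the Hedgehog pathway, with 6 of 12 genes higher and none lower (6 adjusted over the list alone, 11 higher and 0 lower with quantile normalization; camera adjusted p = 3.72e-07, adjusted p = 0.309 with an estimated correlation). Shh measured 11.7 ± 0.147 FPKM against 6.27 ± 1.12 (0.82, limma adjusted p = 7.89e-04) and Gli1 4.70 ± 0.0891 against 2.37 ± 0.337 (0.77). The follicle stem cell factor Lhx2 rose from 19.5 ± 4.77 to 41.3 ± 2.63 FPKM (1.07, adjusted p = 8.71e-04) and the basal keratin Krt14 fell from 29.3 ± 2.76 to 16.5 ± 0.730 (−0.78). Of 24 outer root sheath and basal genes, 10 rose and 6 fell (12 and 8 adjusted over the list alone, 14 higher and 6 lower with quantile normalization; camera adjusted p = 0.0127, adjusted p = 0.661 with an estimated correlation, and 0.06 without the wild type of the Notch line). Of 22 FGF, EGF and IGF genes, 9 rose and 5 fell (9 and 5 adjusted over the list alone, 10 higher and 3 lower with quantile normalization; camera adjusted p = 0.0011, adjusted p = 0.661 with an estimated correlation). Of 15 immediate early genes, 2 rose (2 adjusted over the list alone, 5 higher and 0 lower with quantile normalization; camera adjusted p = 0.0011, adjusted p = 0.661 with an estimated correlation), Ier3 (0.64) and Dnajb1 (0.49).

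Alarmins and immune markers were also higher in Notch1&2-null follicles, with 7 of 11 alarmins (none lower, 7 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.4e-06, adjusted p = 0.309 with an estimated correlation) and 10 of 18 immune markers rising (none lower, 10 adjusted over the list alone, camera adjusted p = 1.08e-08, adjusted p = 0.309 with an estimated correlation). The antigen presentation gene H2-Aa went from 0.852 ± 0.411 to 5.27 ± 0.401 FPKM (1.78) and Cd74 from 3.37 ± 1.26 to 11.1 ± 0.739 (1.50). Of 10 sebocyte markers 6 fell and none rose (7 fell adjusted over the list alone, camera adjusted p = 0.00599, adjusted p = 0.596 with an estimated correlation). Of 16 melanocyte markers 8 fell and 1 rose (9 and 1 adjusted over the list alone, camera adjusted p = 0.0454, adjusted p = 0.661 with an estimated correlation). This call was lost without the wild type of the Notch line (0.0817) or Notch1&2-null library 1 (0.07) or 2 (0.0543). Of 22 fibroblast markers 2 rose and 2 fell (2 and 2 adjusted over the list alone, 6 higher and 2 lower with quantile normalization; camera adjusted p = 0.0454, adjusted p = 0.661 with an estimated correlation). This call was lost without wild type 2 (0.244), wild type 3 (0.0588), Notch1&2-null library 2 (0.0543) or 3 (0.0693), and with separate spreads (0.0544). Of 19 Wnt genes 4 rose and 2 fell (4 and 2 adjusted over the list alone, 9 higher and 2 lower with quantile normalization; camera adjusted p = 0.049, adjusted p = 0.661 with an estimated correlation). This call was lost without wild type 1 (0.0536) or 2 (0.0574), Notch1&2-null library 1 (0.07), 2 (0.0543) or 3 (0.0518), or Psen1&2-null library 3 (0.0504), and with separate spreads (0.0511).

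Limma called 2608 genes in Notch1&2-null against wild-type libraries, 605 higher and 2003 lower (76.8% lower), and 1425 higher and 1227 lower with quantile normalization. Without Notch1&2-null library 2, the deepest, the count was 1480, and without library 3 it was 1535. Genes called higher numbered 392 and 372 without these libraries and 1008 without wild type 1, and genes called lower 1088, 1163 and 1632. Scaling by the FPKM sum turned the balance, with 1392 higher and 951 lower. With separate spreads it was 1711, and 1573 with only these 2 groups in the fit.

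In Psen1&2-null follicles, keratins of the hair shaft were lower, and their list was the only one in any of the 8 comparisons to pass with an estimated correlation. Of 14 tested, 12 fell and none rose (12 adjusted over the list alone, camera adjusted p = 6.91e-09, adjusted p = 0.0491 with an estimated correlation). Krt31 measured 7.74 ± 0.990 FPKM against 42.5 ± 2.02 (−2.32, SE 0.12, limma adjusted p = 2.38e-07), Krt33b 1.30 ± 0.261 against 23.9 ± 9.05 (−3.39) and Krt86 3.79 ± 0.329 against 15.3 ± 1.18 (−1.77). Of 19 inner root sheath and medulla genes 12 fell and none rose (13 fell adjusted over the list alone, 1 higher and 11 lower with quantile normalization; camera adjusted p = 1.05e-05, adjusted p = 0.6 with an estimated correlation), with Krt72 at 6.32 ± 1.03 FPKM (−3.53) and Krt26 at 4.43 ± 0.216 (−3.23). Gprc5d fell from 29.4 ± 6.55 to 5.89 ± 0.167 FPKM (−2.12).

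The largest rises in Psen1&2-null follicles included Stfa3 (3.14), the haptoglobin gene Hp (10.7 ± 5.95 to 60.3 ± 4.63 FPKM, 2.54), Serpina3n (2.30) and the epidermal gene Krtdap (11.7 ± 4.64 to 40.6 ± 5.52 FPKM, 1.76, limma adjusted p = 1.31e-04). Of 24 outer root sheath and basal genes, 8 rose and 4 fell (11 and 4 adjusted over the list alone, 15 higher and 3 lower with quantile normalization; camera adjusted p = 6.52e-05, adjusted p = 0.6 with an estimated correlation), with Lgr6 at 8.86 ± 0.722 FPKM against 2.55 ± 0.604 (1.48). Of 11 alarmins 4 rose and 2 fell (4 and 2 adjusted over the list alone, 7 higher and 1 lower with quantile normalization; camera adjusted p = 6.52e-05, adjusted p = 0.6 with an estimated correlation). Of 12 Hedgehog genes 3 rose and none fell (3 adjusted over the list alone, 6 higher and 0 lower with quantile normalization; camera adjusted p = 2.9e-04, adjusted p = 0.6 with an estimated correlation). Of 18 immune markers 3 rose and 1 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.0526). The fibroblast proteoglycan gene Dcn rose from 153 ± 22.1 to 324 ± 11.8 FPKM (1.09) and the dermatopontin gene Dpt fell from 20.3 ± 2.88 to 8.02 ± 0.290 (−1.23).

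Of 17 dermal papilla markers in Psen1&2-null follicles, 5 rose and 3 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.0148, adjusted p = 0.6 with an estimated correlation, and 0.0773 with quantile normalization). Of 22 FGF, EGF and IGF genes, 8 rose and 5 fell (9 and 9 adjusted over the list alone, camera adjusted p = 0.0353, adjusted p = 0.874 with an estimated correlation), with the test upward, a median of 0.04 and a mean of −0.02, and the call was lost without Psen1&2-null library 2 (0.0553) and with quantile normalization (0.0908). Of 10 sebocyte markers 6 fell and none rose (7 fell adjusted over the list alone, camera adjusted p = 0.0353, adjusted p = 0.6 with an estimated correlation, and 0.0514 without the wild type of the Psen line). The endothelial and pericyte genes Cdh5 (−0.85) and Rgs5 (−0.82) fell, although their list did not pass (camera adjusted p = 0.591). Limma called 2900 genes, 439 higher and 2461 lower (84.9% lower), against 1364 higher and 1289 lower with quantile normalization, and 1652 with only the 2 groups in the fit. With separate spreads the count was 2053, and without Psen1&2-null library 1 the genes called higher numbered 270.

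In RBPjk-null follicles, immune and fibroblast markers rose together with the loss of hair keratins. Of 18 immune markers 14 rose and none fell (15 rose adjusted over the list alone, camera adjusted p = 1.88e-17, adjusted p = 0.066 with an estimated correlation). Lyz2 measured 110.3 ± 21.3 FPKM against 19.5 ± 5.46 (2.46, SE 0.18, limma adjusted p = 4.36e-06), Tyrobp 26.5 ± 3.98 against 4.16 ± 1.2 (2.43) and the macrophage mannose receptor gene Mrc1 5.84 ± 0.0902 against 2.54 ± 0.205 (0.95). Of 22 fibroblast and sheath markers 16 rose and none fell (18 rose adjusted over the list alone, 19 higher and 0 lower with quantile normalization; camera adjusted p = 7.46e-13, adjusted p = 0.266 with an estimated correlation), among them Thy1 (11.4 ± 3.06 to 40.3 ± 2.49 FPKM, 1.76), Col6a3 (0.96) and Fbn1 (0.77). Of 11 alarmins 7 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 1.58e-07, adjusted p = 0.24 with an estimated correlation), with S100a9 at 20.4 ± 2.33 FPKM (3.52) and the cytokine gene Il1b at 3.43 ± 0.724 against 0.0904 ± 0.0342 (2.01).

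**Figure D3:**
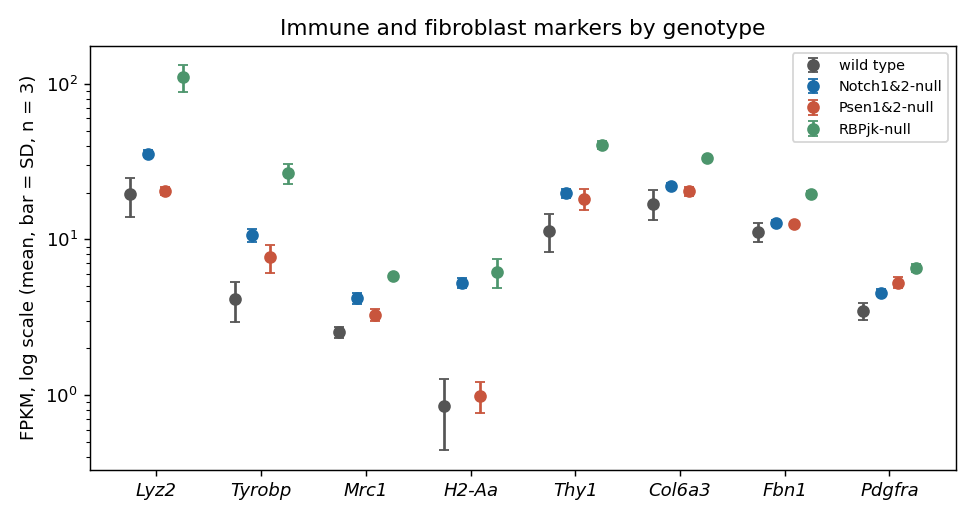
FPKM of 4 immune and 4 fibroblast markers on a log axis, as the mean of each group of 3 libraries with bars for the SD. The RBPjk-null libraries had the highest mean of each of the 8 genes, for Lyz2 110.3 FPKM against 19.5 in wild types.

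The hair keratins of RBPjk-null follicles fell, with 11 of 14 hair shaft keratins lower (none higher, 12 adjusted over the list alone, camera adjusted p = 2.12e-07, adjusted p = 0.066 with an estimated correlation) and 9 of 19 inner root sheath and medulla genes lower and 1 higher (11 and 1 adjusted over the list alone, camera adjusted p = 9.68e-05, adjusted p = 0.524 with an estimated correlation). Krt72 stood at 8.89 ± 0.716 FPKM (−3.09) and Krt26 at 5.57 ± 0.0781 (−2.95). Of 16 melanocyte markers 10 fell and none rose (11 fell adjusted over the list alone, camera adjusted p = 3.27e-04, adjusted p = 0.548 with an estimated correlation), with Tyrp1 going from 64.9 ± 14.6 to 22.2 ± 2.26 FPKM (−1.49, limma adjusted p = 3e-05) and Dct from 82.3 ± 14.8 to 41.0 ± 1.69 (−0.97). Of 24 outer root sheath and basal genes 9 rose and 2 fell (10 and 2 adjusted over the list alone, 12 higher and 1 lower with quantile normalization; camera adjusted p = 5.66e-05, adjusted p = 0.548 with an estimated correlation). Of 12 Hedgehog genes 5 rose and none fell (6 rose adjusted over the list alone, camera adjusted p = 1.5e-04, adjusted p = 0.524 with an estimated correlation). Of 22 FGF, EGF and IGF genes 6 rose and 2 fell (8 and 2 adjusted over the list alone, 11 higher and 2 lower with quantile normalization; camera adjusted p = 0.0065, adjusted p = 0.583 with an estimated correlation). Igfbp3 went from 5.15 ± 1.28 to 20.2 ± 0.541 FPKM (1.81) and Sfrp2 from 1.91 ± 0.322 to 9.09 ± 1.51 (1.79).

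Limma called 2702 genes in RBPjk-null against wild-type libraries, 692 higher and 2010 lower (74.4% lower), and 1340 higher and 1499 lower with quantile normalization. Against the wild types of the Notch and RBPjk lines alone, which like the RBPjk-null libraries had Y-linked and almost no Xist expression, the count was 2715. With separate spreads it was 1866, and with only the 2 full groups in the fit 1112. Genes called higher numbered 1043 without wild type 1 and 445 without RBPjk-null library 2, and genes called lower 1281 without RBPjk-null library 3.

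The genes called in the 3 genotypes overlapped. In the same direction in all 3, 1228 genes were called, 1056 lower and 172 higher, where independent lists of these sizes would share 98.1 lower and 1.82 higher. Unchanged groups simulated against the same wild types shared 3.84 genes on average over 50 simulations. For the pairs, 1363 genes were lower and 244 higher in both Notch1&2-null and Psen1&2-null follicles (independent lists 490.4 and 26.4), 1300 and 301 in Notch1&2-null and RBPjk-null (400.6 and 41.6), and 1425 and 230 in Psen1&2-null and RBPjk-null (492 and 30.2). The covariance of the log2 fold changes over the 10051 genes was 0.135, 0.149 and 0.139 for these pairs, against 0.0419, 0.0411 and 0.0415 in the simulations, and Pearson's r was 0.711, 0.731 and 0.694 against 0.654, 0.644 and 0.658. These values are across genes, which are not independent replicates. The 3 wild types cannot be split into 2 sets of at least 2 libraries, so part of the overlap may come from the shared controls. In 1 genotype only, 2107 of the 4541 genes called in any passed the threshold, which does not show a difference between genotypes. With quantile normalization 1043 genes were shared, 542 lower and 501 higher, so the balance toward lower genes depends on the scaling. With separate spreads 790 were shared, and 328 by an unadjusted p and a 1.5-fold bound.

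Direct comparisons asked whether the 3 mutants could be told apart. Between Notch1&2-null and Psen1&2-null follicles, hair shaft keratins were higher in the former, with 9 of 14 higher and none lower (11 higher adjusted over the list alone, camera adjusted p = 8.5e-07, adjusted p = 0.106 with an estimated correlation). Psors1c2 measured 56.4 ± 4.13 FPKM in Notch1&2-null and 10.4 ± 0.823 in Psen1&2-null libraries (2.33, SE 0.15, limma adjusted p = 1e-05), and the actin-binding protein gene Tmsb10 118 ± 12.3 and 37.3 ± 3.82 (1.63). Of the inner root sheath cuticle keratins, Krt72 and Krt26 went the other way, with Krt72 lower (−2.66, adjusted p = 1.48e-07) and Krt26 at −2.09 (adjusted p = 1.02e-07) in Notch1&2-null libraries. Krt73 stood at 26.6 ± 1.51 FPKM in Notch1&2-null and 28.2 ± 0.359 in Psen1&2-null libraries. Rpph1, the RNA of ribonuclease P, was lower as well (−1.93). Of 18 immune markers 9 were higher and none lower in Notch1&2-null libraries (11 and 1 adjusted over the list alone, 8 higher and 1 lower with quantile normalization; camera adjusted p = 1.3e-05, adjusted p = 0.749 with an estimated correlation), with Cd74 at 11.1 ± 0.739 against 2.89 ± 0.455 FPKM (1.64).

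Of 21 hair matrix regulators 4 were higher and none lower in Notch1&2-null than in Psen1&2-null libraries (10 and 1 adjusted over the list alone, 9 higher and 0 lower with quantile normalization; camera adjusted p = 5.66e-05, adjusted p = 0.749 with an estimated correlation). Of 15 immediate early genes 4 were higher and none lower (8 and 0 adjusted over the list alone, camera adjusted p = 9.92e-04, adjusted p = 0.749 with an estimated correlation). The alarmin call (1 of 11 higher, 2 adjusted over the list alone, camera adjusted p = 0.0446, adjusted p = 0.749 with an estimated correlation) was lost without Notch1&2-null library 1 (0.0519) or 3 (0.0696), Psen1&2-null library 1 (0.0648) or 3 (0.0559), or RBPjk-null library 2 (0.0515). Limma called 743 genes, 489 higher and 254 lower in Notch1&2-null libraries (34.2% lower), 763 and 680 with quantile normalization, and 2050 and 248 with scaling by the FPKM sum. The count was 1225 and 1246 without wild type 1 and 2. Leaving out Notch1&2-null library 1, 2 or 3 gave 337, 298 or 268, and Psen1&2-null library 1, 2 or 3 gave 348, 278 or 313. With separate spreads it was 1687.

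Between Notch1&2-null and RBPjk-null follicles, fibroblast and immune markers were lower in the former. Of 22 fibroblast markers 12 were lower and none higher (19 lower adjusted over the list alone, 0 higher and 16 lower with quantile normalization; camera adjusted p = 6.74e-14, adjusted p = 0.436 with an estimated correlation). Of 18 immune markers 9 were lower and none higher (11 lower adjusted over the list alone, camera adjusted p = 3.13e-09, adjusted p = 0.436 with an estimated correlation). Hair matrix regulators were higher, 6 of 21 (none lower, 8 higher adjusted over the list alone, 10 higher and 0 lower with quantile normalization; camera adjusted p = 1.41e-05, adjusted p = 0.723 with an estimated correlation). Krt72 (−3.10, SE 0.11, limma adjusted p = 2.59e-08) and Krt26 (−2.37) were lower, as was the imprinted gene Mest (11.5 ± 0.167 against 40.4 ± 2.22 FPKM, −1.73). Bcap29 (7.62 ± 0.979 against 1.96 ± 0.416 FPKM, 1.55) and Lyg2 (1.25) were higher in Notch1&2-null libraries.

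Lists near the threshold between these genotypes were the melanocyte markers (3 of 16 higher, 8 higher and 3 lower adjusted over the list alone, 8 higher and 1 lower with quantile normalization; camera adjusted p = 0.0483, adjusted p = 0.723 with an estimated correlation), endothelial markers (0 of 6 by limma over all genes, 3 lower at an unadjusted p under 0.05, 1 lower adjusted over the list alone, 0 higher and 1 lower with quantile normalization; camera adjusted p = 0.0483, adjusted p = 0.723 with an estimated correlation) and adipocyte markers (2 of 10 lower, 2 adjusted over the list alone, 1 higher and 2 lower with quantile normalization; camera adjusted p = 0.0391, adjusted p = 0.723 with an estimated correlation). The melanocyte call was lost without Notch1&2-null library 3 (0.0614), Psen1&2-null library 2 (0.0508) or RBPjk-null library 1 (0.0738) or 3 (0.0679). The endothelial call was lost without Notch1&2-null library 1 (0.0876), Psen1&2-null library 2 (0.0508) or RBPjk-null library 2 (0.0731) or 3 (0.0732), and the adipocyte call with quantile normalization (0.0874). Without the wild type of the RBPjk line, 11 lists passed in place of 6. Limma called 555 genes, 203 higher and 352 lower in Notch1&2-null libraries (63.4% lower), against 646 and 572 with quantile normalization. Scaling by the FPKM sum turned the balance, with 1336 higher and 310 lower. The count was 885 and 876 without wild type 1 and 2. It was 249, 172 or 160 without Notch1&2-null library 1, 2 or 3, and 184 or 171 without RBPjk-null library 1 or 2. Genes called higher numbered 121 without RBPjk-null library 3. With separate spreads it was 1294.

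Between Psen1&2-null and RBPjk-null follicles, immune, fibroblast and endothelial markers were lower in the former: 14 of 18 immune markers (none higher, 15 lower adjusted over the list alone, camera adjusted p = 4.38e-17, adjusted p = 0.133 with an estimated correlation), 17 of 22 fibroblast markers with 1 higher (21 and 1 adjusted over the list alone, camera adjusted p = 4.55e-12, adjusted p = 0.3 with an estimated correlation) and 3 of 6 endothelial markers (3 adjusted over the list alone, camera adjusted p = 8.06e-04, adjusted p = 0.3 with an estimated correlation). Lyz2 measured 20.5 ± 1.31 against 110.3 ± 21.3 FPKM (−2.35, SE 0.18, limma adjusted p = 6.62e-05) and the Fc receptor subunit gene Fcer1g 7.15 ± 0.910 against 34.4 ± 4.12 (−2.12). Hair shaft keratins were lower too, 7 of 14 (none higher, 10 lower and 1 higher adjusted over the list alone, camera adjusted p = 3.02e-05, adjusted p = 0.133 with an estimated correlation), and 3 of 11 alarmins (4 adjusted over the list alone, camera adjusted p = 4.07e-04, adjusted p = 0.398 with an estimated correlation). Of 16 melanocyte markers 6 were higher and none lower (6 and 1 adjusted over the list alone, camera adjusted p = 8.66e-04, adjusted p = 0.701 with an estimated correlation). Bcap29 (11.2 ± 0.426 against 1.96 ± 0.416 FPKM, 2.05) and Metap1d (1.33) were higher, and the Y-linked Eif2s3y lower.

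Of 19 inner root sheath and medulla genes 3 were lower and none higher in Psen1&2-null than in RBPjk-null libraries (6 lower adjusted over the list alone, 2 higher and 3 lower with quantile normalization; camera adjusted p = 0.0478, adjusted p = 0.781 with an estimated correlation). The call was lost without wild type 3 (0.0514), Notch1&2-null library 1 (0.0545) or 2 (0.0529), Psen1&2-null library 1 (0.0572) or 2 (0.073), or RBPjk-null library 1 (0.0554) or 3 (0.102). Limma called 781 genes, 186 higher and 595 lower in Psen1&2-null libraries (76.2% lower), against 704 and 651 with quantile normalization. The count was 1213 without wild type 2. It was 467, 338 or 371 without Psen1&2-null library 1, 2 or 3, and 346 or 337 without RBPjk-null library 1 or 2. Genes called higher numbered 123 without Notch1&2-null library 3 and 93 without RBPjk-null library 3. With separate spreads it was 1663.

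The Notch1&2-null and Psen1&2-null follicles, which lack the receptors or the protease, were also set together against the RBPjk-null follicles. Immune markers (14 of 18, 15 adjusted over the list alone, camera adjusted p = 8.87e-17, adjusted p = 0.147 with an estimated correlation) and fibroblast markers (18 of 22, 21 adjusted over the list alone, camera adjusted p = 6.52e-16, adjusted p = 0.332 with an estimated correlation) were lower with none higher, as were 3 of 11 alarmins (3 adjusted over the list alone, 1 higher and 3 lower with quantile normalization; camera adjusted p = 0.00263, adjusted p = 0.582 with an estimated correlation) and 2 of 6 endothelial markers (4 adjusted over the list alone, camera adjusted p = 0.00179, adjusted p = 0.332 with an estimated correlation). Mest (−1.88, SE 0.11, limma adjusted p = 4.99e-06), Lyz2 (−1.97), Npy (−1.98), Krt72 (−1.77) and Wfdc17 (−1.59) had the largest falls. Xist (5.21), Tsix (3.18), Bcap29 (1.80), Metap1d (1.16) and the histone gene Hist1h2bf (1.07), whose family is near-identical, had the largest rises. The Hist1h2bf call was lost without Notch1&2-null library 1 (0.0536), 2 (0.0577) or 3 (0.0679), Psen1&2-null library 1 (0.0507) or 2 (0.0645), or RBPjk-null library 2 (0.134) or 3 (0.0984), and the Xist call without RBPjk-null library 2 (0.0515). Of 16 melanocyte markers 4 were higher (7 and 1 lower adjusted over the list alone, 7 higher and 1 lower with quantile normalization; camera adjusted p = 0.00197, adjusted p = 0.7 with an estimated correlation).

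Of 21 hair matrix regulators 2 were higher in this comparison (5 adjusted over the list alone, 5 higher and 0 lower with quantile normalization; camera adjusted p = 0.0326, adjusted p = 0.803 with an estimated correlation, and 0.0623 without RBPjk-null library 1). Of 10 adipocyte markers 2 were lower (4 adjusted over the list alone, camera adjusted p = 0.0374, adjusted p = 0.7 with an estimated correlation). This call was lost without Psen1&2-null library 1 (0.0553) or RBPjk-null library 1 (0.052) and with quantile normalization (0.0775). Limma called 643 genes, 169 higher and 474 lower in the joined groups (73.7% lower), against 615 and 591 with quantile normalization. Scaling by the FPKM sum turned the balance, with 514 higher and 405 lower. The count was 410, 367 or 354 without Notch1&2-null library 1, 2 or 3, 372 without Psen1&2-null library 2, and 239 or 213 without RBPjk-null library 1 or 2. Genes called higher numbered 271 or 269 without wild type 1 or 2, 93 or 101 without Psen1&2-null library 1 or 3, and 78 without RBPjk-null library 3. With separate spreads it was 1338.

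Clustering separated wild type from mutant and the mutants from each other. The series' design text states that it did not tell the mutants apart, by genes and a distance not given in the sources used here. For each of the 9 mutant libraries the nearest other mutant library, by Pearson's r over 10051 genes, had the same genotype (one-sided exact permutation p = 0.00357 over 1680 arrangements of the labels). With the 1000 most variable genes this held for 8 of 9 (exact p = 0.00714). Cutting the tree of 13 libraries into 2 clusters put the wild types and the mixture apart from the mutants, and cutting the 9 mutants into 3 put each genotype in its own cluster. The r between libraries was 0.976 to 0.982 within Notch1&2-null, 0.963 to 0.970 within Psen1&2-null, 0.964 to 0.968 within RBPjk-null and 0.948 to 0.953 within wild types. It was 0.940 to 0.964 between mutant genotypes and 0.904 to 0.941 between wild types and mutants, and the mixture had an r of 0.961 to 0.966 with the wild types. Mouse line and sex varied with the genotype, so its clusters are also clusters by line. The permutation ignores that libraries may share animals.

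**Figure D4:**
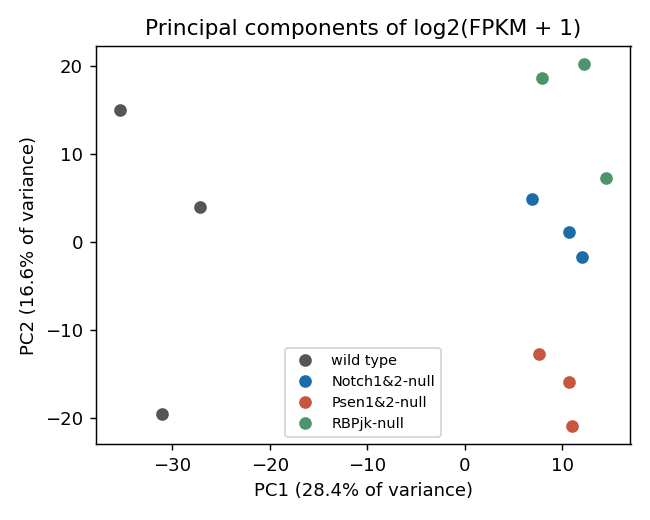
Positions of the 12 libraries on the first principal components of log2(FPKM + 1) over 10051 genes, with the share of variance of each on its axis (28.4% and 16.6%). The wild types lie between −35.4 and −27.2 on PC1 and the mutants between 6.88 and 14.5, and the Psen1&2-null and RBPjk-null libraries lie apart on PC2.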

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

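Of the tests in this part, those on shared animals, on depth and on abundant genes in Notch1&2-null libraries were chosen after the result was seen.

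The 3 genotypes gave different effects against the same wild types, by tests of the differences themselves. Limma called 743 genes between Notch1&2-null and Psen1&2-null, 555 between Notch1&2-null and RBPjk-null, 781 between Psen1&2-null and RBPjk-null, and 643 between the first 2 genotypes together and RBPjk-null. In the last comparison camera called 7 lists, with median log2 differences of −0.92 for immune, −0.61 for fibroblast, −0.35 for endothelial, −0.26 for adipocyte and −0.24 for alarmin genes, and of 0.23 for melanocyte and 0.10 for hair matrix genes. None of these 7 passed with an estimated correlation, and 3 of the 25 lists did at an unadjusted p. The largest gene differences in it were those of Xist (5.21), Tsix (3.18), Bcap29 (1.80), Metap1d (1.16) and Hist1h2bf (1.07), and of Npy (−1.98), Lyz2 (−1.97), Mest (−1.88), Krt72 (−1.77) and Wfdc17 (−1.59). The sex of the animals and the mouse line differed between these groups, so neither could be separated from the genotype. The call of Hist1h2bf was lost without any single Notch1&2-null library, Psen1&2-null library 1 or 2 or RBPjk-null library 2 or 3, and that of Xist without RBPjk-null library 2.

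Other splits of the same libraries were counted for each result over all genes, each fitted as 2 groups of the libraries compared, so the real values differ from the counts of the joint fit. For all mutants against wild type, 1 of 100 splits, the real one, gave as many genes (2566, with the highest other at 169), and likewise for the criterion of the series (702 against 281). Chance can be excluded for both only if the 12 libraries count as independent. Libraries of a genotype may share animals, splits that keep the 4 groups whole are too few to reach a share under 0.05, and with each genotype averaged to 1 value the count was 539. Splits of 3 against 3 libraries are too few to reach a share under 0.05. The real values and highest others were 1573 and 0 for Notch1&2-null, 1652 and 1 for Psen1&2-null and 1112 and 1 for RBPjk-null against wild type. Between genotypes they were 1824 and 1 for Notch1&2-null and Psen1&2-null, 918 and 3 for Notch1&2-null and RBPjk-null, and 960 and 3 for Psen1&2-null and RBPjk-null. For the joined genotypes against RBPjk-null, 2 of 84 splits gave as many genes, the real one with 584 and that of the Psen1&2-null libraries against the rest with 780, so the libraries were structured by genotype.

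The replicates of each mutant genotype differed less from each other than the wild types did. The values argue against greater depth of the mutant libraries as the whole cause, since the lowest ratio of wild-type to mutant spread was still 1.34 among the 1132 genes over 20 FPKM. Differences between the mouse lines are a candidate source, as the deviations of each wild type matched those of its own line's mutants with a mean r of 0.13, the highest of 6 matchings (others −0.10 to 0.03). Libraries of a genotype drawn from the same animals may add to it, which the labels do not state. In Notch1&2-null libraries the CV of Xist was 2.26%, against a median of 6.46% for 561 genes at 20 to 40 FPKM. Of these, 8.91% had a lower CV. Y-linked genes, also present there, had CVs of 7.06% (Ddx3y) to 12.0% (Kdm5d), so this stays open.

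Immune and fibroblast markers were higher in RBPjk-null libraries. A lower share of follicle cells would raise the markers of all other cell types alike only if the other captured tissue kept its make-up. The median of 10 adipocyte markers was −0.03, a difference of −1.14 from that of 18 immune markers (two-sided permutation p = 0.00084 over 100000 resamples). The test treats genes as replicates, although markers within each of these lists varied together (estimated correlation 0.333 and 0.319). The medians of 6 endothelial (0.28) and 22 fibroblast markers (0.59) were above 0, which goes with a lower follicle share, so it is argued against only as the whole cause. Against wild types 1 and 3 alone, which like the RBPjk-null libraries had Y-linked expression, 27 of the 40 immune and fibroblast markers were still higher, so a sex difference alone does not account for them. Single markers went against the pattern, as Dcn stood at 222 ± 30.6 FPKM in RBPjk-null but 324 ± 11.8 in Psen1&2-null libraries, and more immune cells and fibroblasts in or around RBPjk-null follicles, from the genotype or the place of capture, stay open and untested.

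More genes were lower than higher in the mutants, with a median of −0.12 (−0.17 to −0.06 on leaving out 1 library). If a few abundant genes took a larger share, scaling without the 10 most abundant genes would bring the median to 0, and it came to −0.0863 (−0.14 to −0.03). Scaling by the FPKM sum brought it to −0.0646 (−0.09 to −0.05), and neither cause can be told apart from a real shift over all mutants, as both scalings moved the median only part of the way. In Notch1&2-null libraries the 10 most abundant genes held at most 13.04% of the FPKM sum, where 19.7% would be needed at equal sums to give the shift. The sums were not equal, with means of 160660 there and 181593 in wild types. Scaling by them turned the balance in the Notch1&2-null comparison to 1392 higher and 951 lower. A larger FPKM share of these genes alone is argued against, while their share of fragments was not measured and differing sums stay open. Quantile normalization balances higher (1624) and lower (1576) genes by its construction and so says nothing on the cause of the shift.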

How the results depend on the processing

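The settings chosen after the values had been seen are those named with the alternatives above. Counts are of genes called by limma unless stated otherwise, and the cause of a difference was not tested except where named.

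Against wild type, a filter at 5 FPKM gave 1803 genes for all mutants, 1421 for Notch1&2-null, 1576 for Psen1&2-null and 1352 for RBPjk-null, with fewer genes to call from. A fit of only the groups compared gave 1573, 1652 and 1112 for the genotypes and for all mutants equals the fit reported. Separate spreads gave 1860 for all mutants, and 1711, 2053 and 1866 for the genotypes. Each genotype averaged to 1 value gave 539, and 604 when paired with its line's wild type, with fewer degrees of freedom. Leaving out 1 library gave 2847 to 3413 for all mutants, 1480 to 2757 for Notch1&2-null, 2030 to 3301 for Psen1&2-null and 1943 to 2691 for RBPjk-null. When this left 2 libraries in a group, the others stood in for its spread.

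Between Notch1&2-null and Psen1&2-null, the filter at 5 FPKM gave 495, quantile normalization 1443, median-ratio scaling 1375, array weights 2587, separate spreads 1687, scaling by the FPKM sum 2298, a fit of only these groups 1824 and leaving out 1 library 268 to 1246. The same settings gave 315, 1218, 1142, 3066, 1294, 1646, 918 and 160 to 885 between Notch1&2-null and RBPjk-null. Between Psen1&2-null and RBPjk-null, the filter gave 375, quantile normalization 1355, median-ratio scaling 1346, array weights 2597, separate spreads 1663 and leaving out 1 library 337 to 1213. For the joined genotypes against RBPjk-null they gave 283, 1206, 1143, 2705, 1338 and 213 to 945, and a fit without wild types 1236. Removing the wild types or giving them their own spread raised these counts, as their larger spread then no longer entered.

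The labels give the mutant genotypes the same replicate numbers. Over 9 pairs of libraries with the same number, r of their deviations ran from −0.0562 to 0.128, and 1 pair was over 0.1, so they share only a number. With a replicate block the 9 mutant libraries gave 1730, 1288, 1685 and 1309 genes in the 4 comparisons between mutants, and without the block 1652, 1243 and 1564 in the first 3.

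For the criterion of the series, a pseudocount of 0.1 gave 1281 genes, as it raises the fold of low genes, and leaving out 1 library 698 to 891. The overlap of all 3 genotypes was 328 genes by an unadjusted p and a 1.5-fold bound, 790 with separate spreads and 843 to 1259 on leaving out 1 library. Clustering put 9 of 9 mutant libraries nearest their own genotype by Spearman correlation too, 8 with the 1000 most variable genes, and 8 of 8 on leaving out any 1 of them.

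Camera with an estimated correlation called 0 of 25 lists for all mutants, 0 for Notch1&2-null, 1 for Psen1&2-null and 0 for RBPjk-null against wild type, and 0 in each of the 4 comparisons between mutants. At an unadjusted p it gave 3, 4, 1 and 4, and 1, 2, 4 and 3. The rotation test fry, which tests a list by itself, gave 11, 9, 9 and 10 lists, and 4, 3, 7 and 8 between mutants, against 11, 12, 8 and 9, and 5, 6, 7 and 7 by camera. Leaving out 1 library gave 10 to 13 lists for all mutants, 9 to 13, 7 to 12 and 9 to 12 for the genotypes, and 4 to 6, 4 to 11, 6 to 9 and 6 to 10 between mutants.

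Psen2 turned to 0.0105 with median-ratio scaling and ran from −0.26 to 0.14 on leaving out 1 library. Of the other gene values given, 131 of 134 passed with the same sign under the 17 alternatives run for single genes, which were each library left out, quantile normalization, median-ratio scaling, a pseudocount of 0.1, the mixture added and separate spreads. Notch2 in RBPjk-null libraries lost its call with quantile normalization and median-ratio scaling, and the other 2 on leaving out 1 library.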

Other observations

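The tests on keratin-associated proteins and on keratins of the inner root sheath were chosen after their values had been seen. Those on the segments around the targeted genes were chosen before.

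Keratin-associated protein genes in the cluster on chromosome 16 fell more than those elsewhere. Outside the families of high-glycine-tyrosine proteins, 7 genes in that cluster had a mean log2 fold change of −1.82 (SD 1.02) in all mutants against wild type, and 25 genes elsewhere one of −0.24 (SD 0.79). The difference was −1.58 (two-sided permutation of the genes, p = 0.00015), −1.57 with quantile normalization, and −1.86 in Notch1&2-null, −1.31 in Psen1&2-null and −1.57 in RBPjk-null libraries. Limma called 6 of the 7 lower, and 10 lower and 3 higher of the 25. The test treats genes as replicates, although genes of a cluster share sequence and may share regulation.

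The 12 high-glycine-tyrosine genes tested, in the families 6, 7, 8, 19, 21 and 22, all lie in the same cluster, and limma called all 12 lower, with a mean of −2.81 (SD 0.99). Krtap8-1 went from 404 ± 177 FPKM in wild types to 145 ± 8.58, 38.2 ± 2.62 and 101 ± 3.91 in Notch1&2-null, Psen1&2-null and RBPjk-null libraries. Their mean lay 2.22 below that of the 32 genes of other families, but only 0.98 below that of the 7 in the same cluster. The falls of family 19 prompted this comparison, and without that family the difference within the cluster was −0.35 (95% confidence interval −1.31 to 0.60, exact permutation p = 0.406). The protein class alone thus does not account for the falls in the cluster, and whether it adds to place stays open, as 7 genes on each side leave a wide interval. Family 16 was left out, as its class was not certain. A candidate explanation for the fall of the cluster is a missing or delayed layer of the follicle that expresses it. Counting cells that express Krt72 or Krtap19-1 by in situ hybridization on sections of the same age would tell a loss of cells from a lower level per cell.

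In the inner root sheath, the keratins of the cuticle may have fallen more than those shared by its layers, a hypothesis drawn from the falls of Krt72 and Krt26. Krt26, Krt72 and Krt73 had a mean log2 fold change of −3.31 in all mutants, against −0.58 for Krt25, Krt27, Krt28 and Krt71. Only 1 of the 35 choices of 3 among these 7 keratins, the real one, gave as low a difference (exact one-sided p = 0.0286). This is the smallest p that 35 choices can give, and as the falls of Krt72 and Krt26 prompted the test, it is no independent evidence. The means were −4.51 and −0.43 in Notch1&2-null, −2.89 and −0.73 in Psen1&2-null and −2.53 and −0.56 in RBPjk-null libraries. Krt73 fell less than Krt26 and Krt72, to 26.6 ± 1.51 FPKM in Notch1&2-null libraries from 111 ± 26.4 in wild types. The 7 keratins are not independent, and the test treats genes as replicates.

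Segments carried along with a targeted allele may hold variants of the strain in which it was made. Other genes within 10 Mb of each targeted locus were compared between its genotype and the other mutants. The mean size of the difference was ranked among random windows of that width. For Rbpj, 26 genes lay at percentile 97.3, with 4 of them called (15.4%, against 6.40% of all genes), among them Sod3 (higher by 0.72, adjusted p = 0.00339) and Pi4k2b (higher by 0.73, adjusted p = 0.0258). Pi4k2b stood at 8.97 FPKM in RBPjk-null libraries and 9.15 in wild types, so its difference lies in the other mutants. The Notch2 window at 83.2 decides neither way, and those of Notch1, Psen1 and Psen2 at 40.1, 36.0 and 68.6 argue against such an excess. Linkage near Rbpj stays open, and variants in reads there would test it. The percentiles are not adjusted for 5 windows.

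The wild types and the mutants of a line may share background variants as well. The r of 0.13 between deviations of the same line would go with that or with a shared sex. Littermate wild types of each line, at least 3 per line and matched for sex, would separate line and sex from genotype and give each comparison controls. A direct test of whether RBPjk loss adds immune cells would count Lyz2-positive cells in and around follicles of all 3 genotypes, since 27 of 40 immune and fibroblast markers stayed higher against wild types 1 and 3 alone.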
